A study of Homo sapiens with 3 samples.

How the data were processed

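Total RNA from UACC62 melanoma cells was compared on 3 two-colour Agilent whole human genome arrays, each with an shp62 sample in Cy5 and an shControl sample in Cy3 from day 6. Group and direction were taken from the channel labels, and each array was treated as 1 replicate pair. The labelling protocol cites a single-colour kit, which does not match the 2 channels of the files and labels; the labels were followed. No array carried the dyes the other way round. Each array was on a slide of its own, so slide and replicate coincide and no slide block could be fitted.

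The spot and background intensities were written by Agilent Feature Extraction 10.7.1.1, per the file headers, as median pixel brightness per channel with no normalization. The same files hold processed intensities that the scanner software had background-subtracted and dye-normalized, per the file headers, and log10 ratios made from these, per the file headers. The submitters' processing notes name limma, with no version or role. The authors' deposited value table holds log2 ratios whose normalization is not given in the sources used here. Set against each array, its columns had medians of 0.0126, 0.0174 and 0.0193 and correlated with the ratios computed here at 0.997, 0.998 and 0.998 across spots with slopes of 1.01, 1.00 and 0.977, which places them on a log2 scale as Cy5 over Cy3. How the authors corrected and centred them stays unknown.

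Each array held 45015 spots, of which 1639 were controls and 43376 measured 41000 probes. The median spot intensity was 200.0, 179 and 269 in Cy3 and 455, 479 and 647 in Cy5 for replicates 1, 2 and 3, over a median local background of 21, 19 and 19 in Cy3 and 53, 55 and 56 in Cy5. Probes well above background numbered 31392, 31850 and 33075 in Cy3 and 30233, 32995 and 33347 in Cy5. The scanner software's quality summary asked for replicate 2 to be evaluated and placed the other arrays in range.

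Signals were processed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on median spot signals and median local background. The plan, written before the data were examined, had named mean spot signals, for which median signals were used instead. Log2 ratios were normalized within each array by loess (span 0.3, control spots at weight 0), with no scaling between arrays. Control spots and spots with a non-uniformity or population outlier mark were left out (132, 721 and 91 probe spots per array), and spots of a probe were averaged. A probe was kept when it was well above background on at least 2 arrays in the same channel, which left 33021 probes (80.5%), of which 33015 had values on at least 2 arrays and 508 had exactly 2. The mean log2 ratio was tested against 0 with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg over all tested probes at a threshold of 0.05. The median SD of a probe over the arrays was 0.119.

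Probes were named through their transcript accessions in a RefSeq gene table of assembly GRCh38.p14. In all, 23680 of 41000 probes (57.8%) matched 1 gene and 17320 stayed unnamed, including 1253 of 24933 probes with a RefSeq transcript accession. The array's own annotation build is older, so no coordinates are given. A gene stood for its kept probe with the highest mean intensity, which gave 14396 genes. Of 2710 genes with more than 1 called probe, 276 had called probes of opposite sign.

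In all, 29 gene lists were fixed before the data were examined. They cover selective autophagy receptors, core autophagy, lysosomal, NRF2, NF-kB, melanocyte lineage, invasive melanoma, epithelial-mesenchymal transition, focal adhesion, extracellular matrix, RNA-binding protein, mRNA decay, G1/S, G2/M, p53, apoptosis, interferon, endoplasmic reticulum stress, heat shock, proteasome, hypoxia and glycolysis, cholesterol, oxidative phosphorylation, ribosomal protein and angiogenic genes, and markers of leukocytes, keratinocytes and epithelia, endothelium and fibroblasts. Of 832 genes written, 798 were measured. Lists were tested with camera (preset inter-gene correlation 0.01, two-sided, adjusted over the 29 lists) on genes with values on all 3 arrays, which leaves out genes with a marked spot; medians of lists are over all measured members unless stated. The named genes were SQSTM1, the 10 genes with the largest positive and the 10 with the largest negative mean among called genes with the same sign on all 3 arrays and a proper symbol, up to 4 members of each list with the smallest p, and FERMT2, IGF2BP1, NFE2L2, MITF and AXL. Some genes that this rule names are not reported here.

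The alternatives were other background corrections (none, subtraction, offsets of 16 and 0), the processed signals, the deposited log2 ratios, median centring, scale and Aquantile normalization, no filter and a stricter one, marked spots kept, eBayes with trend and robust, separate channels with no replicate block, each replicate left out, the mean of a gene's probes, stricter thresholds, camera with an estimated correlation, fry, and 10000 random lists matched on intensity. The array pairs the samples by design, since both samples of a pair were hybridised together.

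The steps were tested on simulated data: Cy5 signals were drawn for the real probes with a smooth dye curve and 200 probes changed, and the fit covered 33015 probes. It recovered 95.5% of probes changed by 2 on the log2 scale, 80.6% at 1 and 19.4% at 0.5, with 0 calls by limma among 32777 unchanged probes. The median estimate was 1.57 for a true 2, 0.80 for a true 1 and 0.38 for a true 0.5, so the offset shrinks ratios toward 0. A list shifted by -1 among 14396 simulated genes passed camera with a preset correlation while 0 of 28 other lists did, and it gave an adjusted p of 0.112 with an estimated correlation. The simulated noise was independent between spots, so the run did not test the preset correlation. No dye effect of single probes was simulated, so the 0 false calls do not bear on such an effect in the real arrays. Figures were drawn with matplotlib.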

Results

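Gene expression was measured in UACC62, an established human melanoma cell line, 6 days after infection with a lentivirus carrying an shRNA against p62, the selective autophagy receptor encoded by SQSTM1 (shp62), or a non-targeting shRNA (shControl). Each of 3 two-colour whole-genome oligonucleotide arrays held 1 shp62 sample labelled with Cy5 and 1 shControl sample labelled with Cy3. The series design describes the 3 pairs as biological replicates. Of 41000 probes per array, 73.7%, 80.5% and 81.3% were well above background in the shp62 channel of replicates 1, 2 and 3, and 76.6%, 77.7% and 80.7% in the shControl channel. No spot was saturated. Log2 ratios of the 3 arrays correlated across probes at 0.921, 0.937 and 0.926 (probes are not independent replicates). Replicate 2 held 609 non-uniform probe spots, against 6 and 11 on the other arrays. All ratios below are shp62 over shControl, as mean log2 ratio ± SD with n = 3 arrays unless stated otherwise.

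The comparison asked which transcripts depended on p62 in melanoma cells, a question that the series title ties to the control of mRNA decay. SQSTM1 itself was 6.08-fold lower in shp62 cells, at -2.60 ± 0.09, and was negative on all 3 arrays (limma adjusted p = 4.15e-06). Its value lay between -2.63 and -1.95 over all alternative settings. Among the genes followed irrespective of their values, FERMT2, which encodes the integrin activator kindlin-2, fell to -1.44 ± 0.10 (adjusted p = 1.22e-05). AXL, a receptor tyrosine kinase, fell to -1.33 ± 0.53. IGF2BP1, an mRNA-binding protein that stabilises transcripts, rose on its brightest probe (0.57 ± 0.12), and its other probe gave 1.32. NFE2L2, which encodes the oxidative stress regulator NRF2, gave -0.48 ± 0.17 after loess normalization but 0.17 after median centring of the arrays. MITF, the melanocyte lineage factor, gave -0.29 ± 0.20 (adjusted p = 0.029 by limma), and its other probes gave -0.46, -0.44 and -0.08. After median centring MITF was called higher (0.37, adjusted p = 0.00600 by limma). The call of a fall was lost with background subtraction, an offset of 0, the processed signals, the deposited ratios, no replicate block, and without replicate 1 (-0.17).

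The transcriptome moved broadly in both directions. Of 14396 genes tested, 4573 were higher and 4419 lower in shp62 cells, and 649 and 1014 of these differed by at least 2-fold. At the probe level, 19182 of 33015 passed (9470 higher, 9712 lower). By at least 2-fold, 1224 probes were higher and 1955 lower, against 1892 and 2594 with an offset of 0. Counts at 2-fold therefore depend on the background correction. With median centring in place of loess, 65.7% of the probes called were higher, against 49.4%, and the median of all probes moved from 0.01 to 0.19. The genes called were then 8042 higher and 3038 lower, 2240 and 495 of them by at least 2-fold, so the balance of directions is relative to the loess baseline. The largest falls were in NAP1L1, a histone chaperone, at -4.47 ± 0.18 (22.2-fold lower), and TOP2A, the DNA topoisomerase of dividing cells, at -4.12 ± 0.35. HMMR at -4.06 ± 0.54, the kinetochore genes CENPF at -4.05 ± 0.48, NUF2 at -3.90 ± 0.27 and SPC25 at -3.67 ± 0.42, and DEPDC1 at -3.89 ± 0.62 (-2.75 on its other probe) followed. The nuclear lamina gene LMNB1 fell to -3.87 ± 0.74, the spindle pole gene ASPM to -3.68 ± 0.39 and the condensin subunit NCAPG to -3.66 ± 0.51. NAP1L1 thus had a lower ratio than the targeted gene, although NAP1L1 and SQSTM1 were each measured by a single kept probe.

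The 10 genes that rose most included 2 matrix metalloproteinases and 2 chemokines. MMP1, interstitial collagenase, rose 20.5-fold (4.36 ± 0.43) and MMP10, another matrix metalloproteinase, 14.2-fold (3.83 ± 0.26). The chemokine genes CCL4 and CCL3 rose to 4.15 ± 0.28 and 4.05 ± 0.05. SERPINB2, an inhibitor of plasminogen activators, reached 3.51 ± 0.34. CD36, a fatty acid scavenger receptor, reached 3.96 ± 0.57, RGS5, a regulator of G protein signalling, 3.77 ± 0.41 (4.40 on its other probe), and the cancer-testis gene PAGE1 3.28 ± 0.20. The cornified envelope genes SPRR2D (3.88 ± 0.21) and SPRR2C (3.49 ± 0.32) rose as well. CCL3, CCL4 and the SPRR2 genes have near-identical copies that a probe could also bind, so their identity within the family is uncertain. All 20 genes kept their direction and call under every alternative run.

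**Figure D1:**
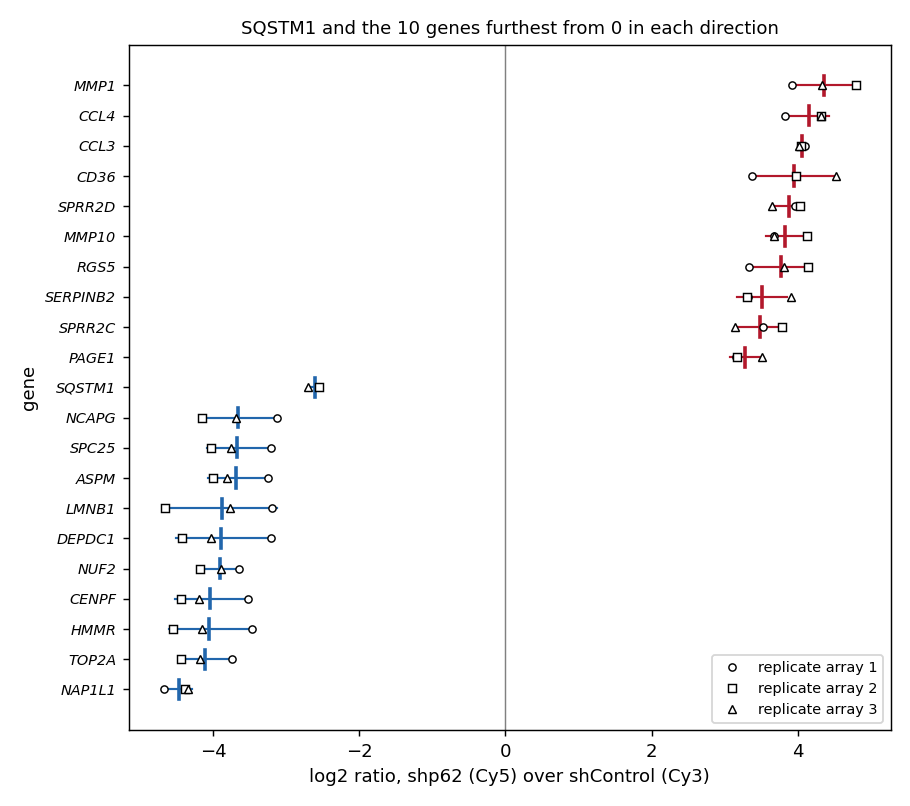
Log2 ratio of shp62 (Cy5) over shControl (Cy3) on the x axis for SQSTM1 and the 10 named genes with the largest positive and the 10 with the largest negative mean, 1 gene per line; open symbols are the 3 replicate arrays, the vertical bar is their mean and the horizontal line spans 1 SD to each side. The arrays lay on the same side of 0 for each gene, from NAP1L1 at -4.47 to MMP1 at 4.36.

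Genes of cell division fell together. All 32 measured G2/M and mitosis genes fell, each by at least 2-fold, with a median of -2.66 (median-centred -2.25). TOP2A, HMMR and CENPF lay lowest. MAD2L1, a spindle checkpoint gene, lay at -3.41 ± 0.18, CCNB2, a mitotic cyclin, at -2.98 ± 0.25, and ECT2, a regulator of cytokinesis, at -2.05 ± 0.07. Of 33 G1/S and replication genes, 31 fell and 2 did not pass, with a median of -1.62. RFC3, a clamp loader subunit, fell to -2.87 ± 0.27 (other probe -1.85), RRM1, a ribonucleotide reductase subunit, to -2.46 ± 0.18, and the helicase subunit MCM7 to -1.86 ± 0.06. Adjusted over the list alone, the counts were again 32 and 31. Both lists stood below other genes by camera with a preset correlation (adjusted p = 2.87e-16 and 1.46e-13). With an estimated correlation neither passed (adjusted p = 0.486 for each). With 3 arrays none of the 29 lists passed this form of camera, which also missed a shifted list in simulated data (adjusted p = 0.112). Its results, here and below, therefore cannot decide for or against a list. Below, a list passed or did not pass by camera at the preset correlation unless another test is named.

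NF-kB target genes rose. Of 29 measured, 22 rose, 4 fell and 3 did not pass, the same counts as when adjusted over the list alone, and the median was 0.53. The list passed camera (adjusted p = 0.000829; adjusted p = 0.486 with an estimated correlation). After median centring the median was 0.86, the median of all probes moved from 0.01 to 0.19, and the list no longer passed (adjusted p = 0.140). IL1B, a pro-inflammatory cytokine, rose 9.28-fold (3.21 ± 0.30), CCL2, a monocyte chemokine, 4.87-fold (2.28 ± 0.42), BIRC3, an inhibitor of apoptosis, 3.55-fold (1.83 ± 0.13) and TNFAIP3, a feedback inhibitor of the pathway, 2.72-fold (1.44 ± 0.22). The 4 members that fell, named after their values were seen, were IL6 at -0.35, TNFAIP2 at -0.53, the subunit gene NFKB1 at -0.81 and the superoxide dismutase SOD2 at -0.82. Leukocyte markers, a fixed list for another cell type, did not pass (5 of 16 rose and 1 fell, adjusted p = 0.175; 4 and 1 adjusted over the list alone), with LYZ at 0.93 ± 0.27, CSF1R at 0.69 ± 0.11, ITGAM at 0.40 ± 0.13 and ITGAX at -0.55 ± 0.01. ITGAX lost its call after median centring (-0.14) and with no replicate block.

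Interferon response genes fell as a list under loess. After median centring their median turned to 0.06 and their mean to -0.09, below the median of all probes (0.19). There the list still passed camera as lower than other genes (adjusted p = 0.0244). Of 36 measured, 20 fell, 4 rose and 12 did not pass (21 and 4 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.00188; adjusted p = 0.486 with an estimated correlation). IFI44 fell to -2.63 ± 0.20, the antiviral effector IFIT1 to -1.83 ± 0.24, OASL to -1.65 ± 0.13 and the guanylate-binding protein GBP2 to -1.31 ± 0.17.

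Cholesterol synthesis genes fell, with a median of -0.59 that became 0.01 after median centring (mean -0.17). There the list still passed camera as lower than other genes (adjusted p = 0.0226). Of 26 measured, 18 fell, 1 rose and 7 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.000162; adjusted p = 0.486 with an estimated correlation). The enzyme genes MSMO1 and SQLE fell to -1.99 ± 0.11 and -1.89 ± 0.29, and INSIG1, a sterol-sensing regulator, to -1.59 ± 0.22. Hypoxia and glycolysis genes also fell as a list, with a median of -0.38 under loess, and no longer passed after median centring (median 0.25, adjusted p = 0.272). Of 32 measured, 20 fell, 3 rose and 9 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.00364; adjusted p = 0.486 with an estimated correlation). PDK1, which restrains pyruvate oxidation, fell to -2.52 ± 0.14 (other probe -1.27) and the lactate transporter SLC16A3 to -1.80 ± 0.07. The glucose transporter SLC2A3 fell to -1.59 ± 0.18 (other probe -0.66) and the hexokinase HK2 to -1.20 ± 0.03 (-0.50 after median centring). Bright probes that carried an outlier mark on replicate 2 entered only 2 arrays and were left out of the list test, which used 27 of the 32 genes; their median was -0.60 under loess and 0.13 after median centring. With the marked spots kept, the adjusted p was 0.00182.

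Lysosomal genes of the TFEB-regulated network rose. Of 34 measured, 19 rose, 4 fell and 11 did not pass (21 and 4 adjusted over the list alone), with a median of 0.30, or 0.89 after median centring (adjusted p = 0.000997; camera adjusted p = 0.00886 under loess; adjusted p = 0.486 with an estimated correlation). SGSH, NEU1 and the proton pump subunit ATP6V0D1 rose to 0.91 ± 0.04, 0.86 ± 0.12 and 0.82 ± 0.05. The acid glucosidase GAA instead fell to -1.36 ± 0.07 (-0.63 after median centring). Core autophagy genes did not pass as a list (16 of 34 rose and 7 fell, also adjusted over the list alone, adjusted p = 0.175, or 0.0408 after median centring). Among them ATG13, of the initiating kinase complex, rose to 1.24 ± 0.19 (other probe 0.59) and MAP1LC3B, the LC3 gene, to 1.09 ± 0.11 (other probes 1.42 and 0.50), while ATG4C, an LC3-processing protease, fell to -1.06 ± 0.08. Of 13 selective autophagy receptors, 6 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.816). Besides SQSTM1, the ferritin receptor NCOA4 fell to -1.65 ± 0.18 and the mitophagy receptor BNIP3 to -0.997 ± 0.11 (-0.28 after median centring), and TOLLIP rose to 0.94 ± 0.07 on its brightest probe but gave -0.01 on its other probe. The median of this list was 0.02, its mean -0.19 and its test direction down.

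NRF2 targets were lower in 17 of 29 cases and higher in 6, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.100). Its median of -0.39 became 0.21 after median centring. AKR1C3 fell to -1.51 ± 0.13, NQO1, a quinone reductase, to -1.16 ± 0.22, AKR1C1 to -1.09 ± 0.15 and TALDO1, of the pentose phosphate pathway, to -0.99 ± 0.08 (-0.25 after median centring). Of 31 endoplasmic reticulum stress genes, 19 rose and 6 fell (20 and 6 adjusted over the list alone), with a median of 0.41 and an adjusted p of 0.0746, and the median was 1.08 after median centring, where the list passed (adjusted p = 0.00163). DNAJB9, TRIB3, SESN2 and CHAC1 rose to 2.26 ± 0.24, 1.90 ± 0.20, 1.47 ± 0.15 and 1.46 ± 0.13. Of 19 heat shock genes, 13 fell and 4 rose (14 and 4 adjusted over the list alone), with a median of -0.51 and an adjusted p of 0.0746, and the median was 0.16 after median centring. The mitochondrial chaperonin HSPE1 fell to -1.96 ± 0.10 (n = 2), HSPA1A to -1.63 ± 0.29 (other probes -0.88 and -0.65), DNAJA1 to -1.19 ± 0.14 (-0.42 after median centring) and CHORDC1 to -1.03 ± 0.08. The endoplasmic reticulum stress and heat shock lists passed once spots with outlier marks were kept (adjusted p = 0.0168 and 0.00871), as did the NRF2 list (0.0374). Against random lists of like intensity the NRF2, endoplasmic reticulum stress and heat shock lists passed (adjusted p = 0.0123, 0.00348 and 0.00994). With an estimated correlation none of these lists passed camera (adjusted p = 0.486 for each).

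Targets of p53 moved both ways (7 of 27 rose and 13 fell, 9 and 13 adjusted over the list alone, adjusted p = 0.395). GDF15, a stress cytokine, rose to 2.54 ± 0.33 (n = 2) and the death receptor FAS to 1.58 ± 0.09, and TP53INP1 fell to -1.41 ± 0.19. Of 26 apoptosis genes, 12 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.709). BIRC5, the mitotic survivin gene, fell to -3.21 ± 0.49, while BAD rose to 0.98 ± 0.08. The apoptosis median was 0.13 with a mean of -0.005.

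Proteasome genes did not pass as a list (9 of 35 rose and 13 fell, 11 and 13 adjusted over the list alone, adjusted p = 0.175). PSMA2 lay at -1.78 ± 0.17 and PSMB4 at -1.21 ± 0.08 (n = 2, and -0.36 after median centring). PSMD13 lay at -0.90 ± 0.23 (-0.37 after median centring) and PSMD11 at -0.69 ± 0.07 (-0.084 and not past after median centring). Oxidative phosphorylation genes went both ways (10 of 42 rose and 16 fell, also adjusted over the list alone, adjusted p = 0.175). UQCRB lay at -1.60 ± 0.18, NDUFV2 at -1.55 ± 0.06, ATP5F1C at -0.89 ± 0.03 (-0.33 after median centring) and COX7C at 1.47 ± 0.14. Ribosomal protein genes stayed near 0 under loess (15 of 55 rose and 12 fell, also adjusted over the list alone, adjusted p = 0.714), although only 13 of them had all 3 arrays and entered the test, and after median centring the median of all 55 was 0.95 and the list passed (adjusted p = 0.00884). RPS19, RPS15 and RPS28 rose to 0.96 ± 0.22, 0.71 ± 0.22 and 0.66 ± 0.02 (n = 2 for RPS28; other probes 0.28, 0.49 and 0.09), and RPL26 fell to -0.81 ± 0.04 (n = 2), against 0.10 after median centring.

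Melanocyte lineage genes were lower in 14 of 27 cases and higher in 4, also adjusted over the list alone, and did not pass as a list (adjusted p = 0.175, median -0.28, or 0.25 after median centring). The list medians of replicates 1, 2 and 3 were -0.53, -0.11 and -0.17. The receptor genes ERBB3 and EDNRB fell to -1.49 ± 0.28 and -1.24 ± 0.09 (other EDNRB probe -0.61) and S100B to -1.07 ± 0.09 (-0.31 after median centring), while GPR137B rose to 1.72 ± 0.17. The invasive melanoma list split (12 of 30 rose and 10 fell, 13 and 10 adjusted over the list alone, adjusted p = 0.682). ITGA2, a collagen-binding integrin, rose 4.71-fold (2.24 ± 0.35), and CCN2, a matricellular protein, and CAV1, of caveolae, fell to -2.33 ± 0.23 and -1.28 ± 0.17 (other CAV1 probe -0.45). Of 20 genes of the epithelial-mesenchymal transition list, 8 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.175, or 0.0408 after median centring). MMP1 and MMP3 (1.70 ± 0.30) rose, S100A4 fell to -0.77 ± 0.13 (-0.16 and not past after median centring), and CD44 gave -0.72 ± 0.12 under loess but 0.04 after median centring.

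Of 34 focal adhesion genes, 12 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.483). The fibronectin receptor subunit ITGA5 rose 5.18-fold (2.37 ± 0.24) and TNS3 rose to 0.90 ± 0.14, next to the fall of FERMT2, and ITGB1 gave -0.59 ± 0.14 under loess but 0.20 after median centring. Of 31 extracellular matrix genes, 11 rose and 10 fell, also adjusted over the list alone (adjusted p = 0.918), with a median of -0.09 (0.58 after median centring), a mean of 0.09 and an upward test direction. FBN1, LUM and COL6A2 rose to 1.38 ± 0.15, 1.03 ± 0.07 and 1.001 ± 0.10, and LAMB2 fell to -1.07 ± 0.08 (-0.45 after median centring). Of 23 angiogenic factors and receptors, 10 rose and 6 fell (10 and 7 adjusted over the list alone, adjusted p = 0.398). ANGPT2, an antagonist of vessel stability, rose 6.43-fold on its brightest probe (2.69 ± 0.30; other probe 0.94), KDR rose to 1.91 ± 0.21 and PDGFC to 1.06 ± 0.07 (other probe 0.32), and ANGPT1, which encodes the opposing ligand, fell 4.16-fold (-2.06 ± 0.19; other probe -1.11).

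Genes of mRNA stability, the subject of the series title, moved in both directions. Of 51 genes of the decay machinery, 15 rose, 21 fell and 15 did not pass, also adjusted over the list alone, and the list did not pass (adjusted p = 0.318, median -0.13, or 0.37 after median centring). The exonuclease XRN1 fell to -1.68 ± 0.06 on its brightest probe and gave -0.21 on its other probe. The exosome subunits EXOSC8 and EXOSC2 fell to -1.61 ± 0.13 and -1.38 ± 0.09 and the decapping factor DCP1B to -1.32 ± 0.04. Of 29 RNA-binding protein genes, 6 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.337, median -0.14, or 0.46 after median centring). HNRNPD, which encodes AUF1, fell to -2.12 ± 0.15 (other probes -1.99 and -0.36). FMR1 fell to -1.98 ± 0.19 and its paralog FXR1 to -1.12 ± 0.09 (-0.48 after median centring).

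None of the 3 remaining lists for other cell types passed camera. Of 13 endothelial markers, 7 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.175 by camera, 0.0469 against random lists of like intensity and 0.00997 by fry), with KDR as above, EMCN at 1.26 ± 0.16, PECAM1 at 1.07 ± 0.36 and VWF at -1.11 ± 0.33. EMCN and PECAM1 were each well above background on 1 of the 3 arrays in shControl, and their values ranged from 1.17 to 3.76 and from 0.87 to 2.63 over all settings, so the size of their rise is uncertain. Of 13 keratinocyte and epithelial markers, 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.175 by camera, 0.938 against random lists and 0.0165 by fry). LAMB3 lay at 1.06 ± 0.20, KRT10 at 0.93 ± 0.26 (n = 2), KRT16 at 0.72 ± 0.14 (other probe 0.35) and KRT18 at 0.48 ± 0.15. KRT16 was well above background on 2 of the 3 arrays in shControl and ranged from 0.54 to 1.86 over the settings. Of 11 fibroblast markers, 4 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.965), with COL3A1 at 1.32 ± 0.32 on its brightest probe (others 0.27 and 0.39; 0.66 to 2.33 over all settings), FAP at -1.39 ± 0.37, and a median of -0.02 against a mean of 0.04. The p53 list likewise had a median of -0.15 and a mean of -0.004, which were 0.31 and 0.55 after median centring. Only the G2/M and G1/S lists had a median below 0 after median centring.

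**Figure D2:**
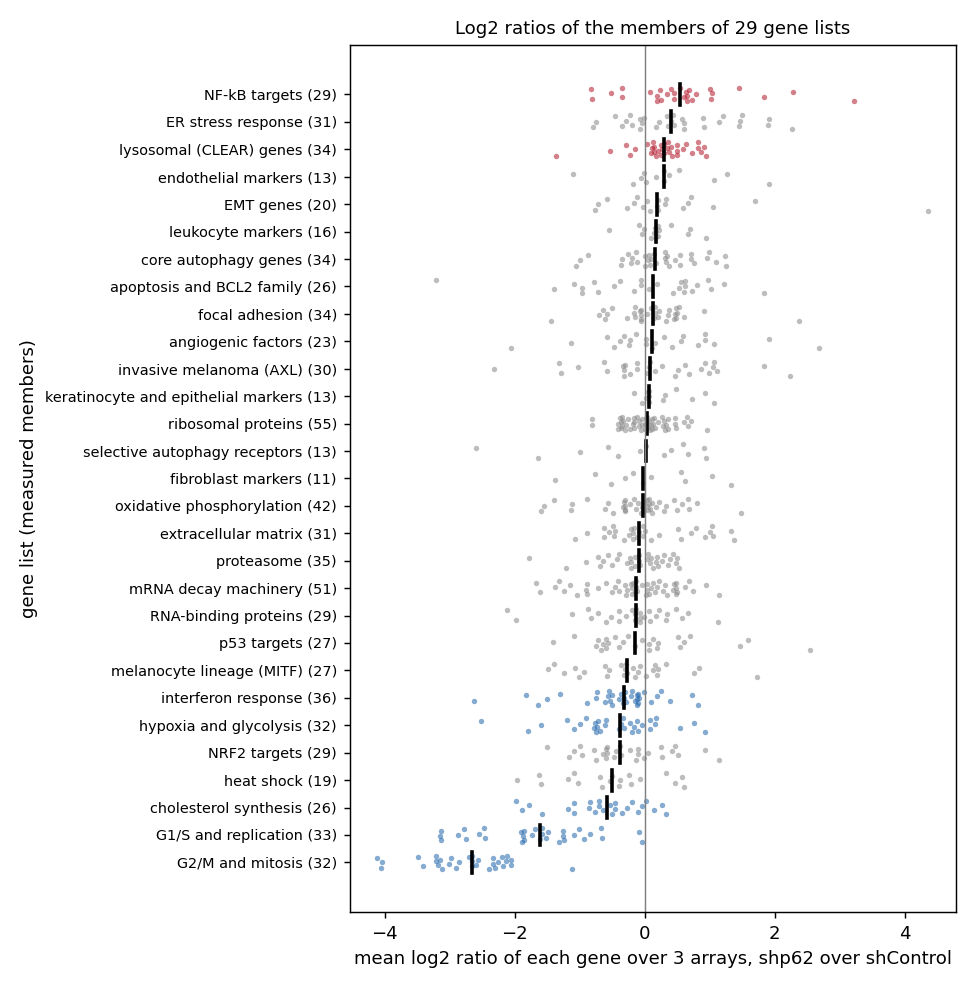
Mean log2 ratio over the 3 arrays (x axis, shp62 over shControl) of each measured member of the 29 gene lists (1 list per line, number of measured members in parentheses); black bars are list medians, red and blue mark lists that rose or fell by camera with a preset correlation, and grey marks lists that did not pass. Medians ran from -2.66 for G2/M and mitosis to 0.53 for NF-kB targets under loess, and the medians of the interferon, hypoxia and cholesterol lists turned to 0.06, 0.25 and 0.01 after median centring. The interferon and cholesterol lists still passed camera there as lower than other genes, and the hypoxia list did not pass.

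The p-values come from limma's moderated test of the mean log2 ratio against 0 over 3 arrays, whose number limits the precision. Because shp62 was labelled with Cy5 on every array, the effect of the shRNA and of the dye on a probe are confounded in these ratios, and the labels name a single shRNA against p62.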

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

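The leukocyte and spike-in tests in this part were chosen after the results were seen. The external RNA spike-ins, which the comparisons do not use, had Cy5 over Cy3 ratios above their design values on every array. The scanner software's offset of observed over expected log10 ratios was 0.491, 0.190 and 0.153 for replicates 1, 2 and 3, that is 3.10-, 1.55- and 1.42-fold, with a mean of 0.278 (SD 0.186). Relative to the spike-ins, the bulk of shp62 transcripts was therefore dimmer than that of shControl. One candidate explanation is less mRNA per unit of total RNA in shp62 cells, and unequal addition of spike-ins or labelling by dye cannot be told apart from it, because every array has the same dye order. Of the 4573 genes called higher, 800 had a log2 ratio above the mean offset, which was 0.92 on the log2 scale. The mean offset rests largely on replicate 1, and with that array's offset left out 2021 genes lay above the mean. The scanner software computed the spike-in offset, whereas the gene ratios used here are shrunk toward 0 (0.80 for a simulated 1). The scales therefore differ, and both counts are approximate and may be too low. The labelling protocol cites a single-colour kit, so the design ratios of the spike-ins are themselves uncertain.

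The fall of cell division genes was set against dye bias. Bias that follows intensity would leave the G2/M median inside the range of random lists of like intensity, but it lay at percentile 0 of 10000 such lists. Bias of single probe sequences would let other probes of the same genes go either way, but 20 of 20 other probes of the G2/M and G1/S genes were negative (100%, 95% exact interval 83.2% to 100%). Both explanations are argued against, and a change in the cells that comes with the shp62 shRNA stays open as a hypothesis, since the effect of this shRNA apart from SQSTM1 was not tested.

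The rise of NF-kB targets and secreted factors was set against dye bias of single probes and admixed leukocytes. Other probes of the NF-kB genes that rose were positive in 7 of 7 cases (100%, exact lower bound 59.0%), too few to exclude a dye bias of single probes. The abundant leukocyte transcripts PTPRC, CD53, CORO1A, TYROBP, LAPTM5 and LYZ had a median log2 ratio of 0.15 (-0.11 to 0.41 with the SD of the array medians). This lay below a cut-off of 1, which was set after the results were seen. LYZ lay highest at 0.93, CD53 gave 0.66 and CORO1A lay lowest at -0.09. CD53 was well above background on 3 arrays in shp62 but on 1 in shControl. These transcripts thus showed no common rise. Admixture stays undecided, because the cut-off had no independent basis and the offset shrinks ratios toward 0.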

How the results depend on the processing

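SQSTM1 and the 20 genes with the largest changes kept their direction and call under every alternative run. The counts of 19182 probes and 8992 genes stayed within 1.5 times under all but 1 choice, a required log2 ratio of at least 1, which by construction left 3179 probes and 1663 genes. Leaving out each replicate gave 15597 to 17781 probes, 7527 to 8211 genes, 8 to 10 lists, 20 of the 20 genes each time, and -2.63 to -2.55 for SQSTM1. The count of lists moved most: 7 with camera at a preset correlation became 0 with an estimated correlation (0 also at an unadjusted p under 0.05) and 11 against random lists of like intensity. With fry, which tests a list against no change rather than against other genes, 21 passed. The estimated correlation was 0.922 for the G2/M list and 0.702 for the G1/S list, against the preset 0.01. In simulated data of the same size a shifted list was also missed with an estimated correlation. The simulated noise was independent between spots, so that run cannot decide whether the preset correlation holds for the real lists. With camera at the preset correlation, all 7 lists passed in each of 17 settings other than median centring, with adjusted p up to 0.0262. Over all 21 alternatives the adjusted p of the G2/M list ranged from 2.46e-25 to 0.486, and that of the NF-kB list from 0.000340 to 0.486. Both upper ends came from camera with an estimated correlation, which passed no list.

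Median centring in place of loess turned the sign of 5 named genes, NFE2L2 to 0.17, MITF to 0.37, CD44 to 0.042, ITGB1 to 0.20 and RPL26 to 0.10. Of these, only MITF was then called (adjusted p = 0.00600 by limma). All 5 were bright, with mean log2 intensities from 14.26 for NFE2L2 to 17.03 for RPL26. With centring the ribosomal list median moved from 0.03 to 0.95, and the proteasome median from -0.09 to 0.62. The leukocyte median moved only from 0.18 to 0.20 and the endothelial median from 0.29 to 0.31. These unequal moves argue against a shift common to all genes. Median centring leaves dye bias that follows intensity in place, but whether this turned the signs was not tested. Median centring cut the log2 ratio of 15 more named genes to under 50%, all of them falls under loess. It called 24457 probes, gave 582 genes a call opposite to the main one and kept 5 of the 7 list calls; the core autophagy, epithelial-mesenchymal transition, endoplasmic reticulum stress and ribosomal lists then passed as well. With no replicate block, on separate channels, 13456 probes and 8 lists passed, MITF and ITGAX lost their calls, and SQSTM1 was unchanged at -2.60. Of the remaining values for named genes, 2329 kept direction and call and 13 lost the call (RPS28 in 2, where its other probe stood for it). For lists, 138 values kept a call and 9 lost it, while 33 gained one and 429 stayed without, some with a median of the other sign. Aquantile leaves log ratios as they are, so it tested nothing. Dim probes limit detection of small changes.

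Turning the sign of 1 array gives 4 splits. The real one gave 19182 probes, 8992 genes and 7 lists; the highest of the others gave 0 probes (limma, 273 at an unadjusted p under 0.05), 0 genes (85 unadjusted) and 9 lists. The number of splits with a count as large was 1, 1 and 3, and 4 splits are too few for a share under 0.05.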

Other observations

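The gene lists in this part were written after the genes with the largest changes had been seen, and the genes named here were chosen after their values were seen; the tests leave out the 40 genes that rose most and the 40 that fell most. Secreted factors of the senescence-associated secretory phenotype rose beyond those top genes. Of 41 remaining members, 26 rose and 8 fell, with a median of 0.66, at percentile 100 of 10000 random lists of like intensity (adjusted p = 0.0008, from the smallest p the draws can give); 23 of the 41 are also in the fixed lists. BMP2 rose to 2.13 ± 0.05, PLAUR, the urokinase receptor, to 1.82 ± 0.05, IL24 to 1.79 ± 0.17 and HBEGF to 1.42 ± 0.24, all n = 3. The left-out members include AREG, an EGF receptor ligand, at 3.24 ± 0.15 and PTGS2, the inducible cyclooxygenase, at 2.77 ± 0.20. Against the theme, IGFBP7 fell to -2.22 ± 0.53, ANGPTL4 to -1.14 ± 0.23 and IGFBP2 to -0.83 ± 0.42, and TNFRSF10C, IGFBP5, TIMP2, IL6 and FGF2 fell less.

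Transcripts that follow ERK activity lay at percentile 99.99, with a median of 0.51 over 23 members, of which 12 rose and 7 fell. SPRED2 and DUSP4, feedback inhibitors of the pathway, rose to 1.23 ± 0.20 and 1.17 ± 0.26, whereas the related SPRED1 fell to -0.46 ± 0.06. ETV4 rose to 0.58 ± 0.23, while ETV1 and ETV5 fell to -0.29 ± 0.03 and -0.30 ± 0.06. EGR1 and FOS fell to -0.42 ± 0.39 and -0.30 ± 0.23 and MYC to -0.72 ± 0.20. Higher output of the ERK pathway stays open as a hypothesis, since related members went both ways.

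Replication-dependent histone genes split by class, counted after the values were seen. Their median of -0.04 over 52 members lay at percentile 28.0, with 23 that rose and 22 that fell. Of the H2B genes 15 of 15 rose (0.83 to 1.26), whereas 4 of 5 H1 and 9 of 10 H4 genes fell and none rose, with medians of -1.95 and -1.07. H4C1, left out as a top gene, rose to 2.56 ± 0.22. Of 12 H2A genes 4 rose and 3 fell, and of 10 H3 genes 4 rose and 6 fell. Histone genes of a class have near-identical sequences, so their probes are not independent and their identity is uncertain. Whether histone transcripts fell with the other S phase genes therefore stays open.

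The rise of SPRR2D and FLG extended to other listed genes of the epidermal differentiation complex. Of 25 remaining members, 14 rose and 0 fell by limma, with a median of 0.21 at percentile 99.5 of random lists. By at least 2-fold, 1 of them rose. The list left out S100 genes of the complex, such as S100A4, which fell to -0.77 under loess (-0.16 after median centring). LORICRIN rose to 2.32 ± 0.19, LCE3D to 0.89 ± 0.35 and IVL to 0.71 ± 0.13, and 11 members did not pass. Of the 13 fixed keratinocyte and epithelial markers, 6 also rose and 0 fell. That list lay at percentile 53.1 of random lists (adjusted p = 0.938) and did not pass camera (adjusted p = 0.175). Whether the rise reached beyond the complex therefore stays open. A change across the listed genes would give a high percentile for them, but a change across the whole gene cluster was not tested. Binding of related family members to each other's probes was not tested either.

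Dye bias of single probe sequences was also weighed for the calls as a whole, with a test written before its result was seen. For genes called at under 2-fold, 83.9% of 3449 other probes shared the sign of the brightest probe (exact 95% interval 82.6% to 85.1%), and at 2-fold or more 93.1% of 853 did (91.2% to 94.7%). For genes not called, 61.6% of 2018 did. Random dye bias of single probes as the whole source of the calls is argued against by these shares, although it remains possible for single genes.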
